A study of Rattus norvegicus with 6 samples.

How the data were processed

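The 6 libraries were made from total RNA of rat liver with poly(A) selection, 2 libraries per group for control, HCC and HCC/NAC, per the labels' protocols. The same protocols state that RNA of 5 animals per group was pooled into 2 replicates; they call the animals mice, while the organism label and the design text say rat. Per the submitters' processing notes, FastQC, STAR, featureCounts and edgeR were used, without versions, and per the file headers each column counts a STAR alignment of 1 library. The genome build, the annotation release and the strand and read-pair settings of the counting are not given in the sources used here. The deposited values are raw counts per Ensembl gene ID: whole numbers for 43360 IDs in the same order in each file, of which 19392 were 0 in every library. No row lacked a gene ID. Reads shared by paralogs or overlapping genes may be assigned or dropped by the counting in ways that are not stated. Duplicate reads and molecular identifiers are not mentioned, so a count is a read or read pair and not a molecule, and limits derived from counts cover counting error only.

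The reference table supplied names for 47357 rat genes but held 0 Ensembl IDs, so 0 of the 43360 IDs received a symbol. The gene lists and cell type markers fixed before the data were examined, and the tests planned on them, could not be used. The rule for named genes asked for a symbol. Its other conditions (adjusted p under 0.05, mean CPM of at least 2, and both libraries of one group above both of the other) were kept, and the 2 IDs with the largest rise and the 2 with the largest fall in HCC against control were named and followed through the other comparisons.

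Counts were analysed with edgeR 4.0.16 in R 4.3.3. IDs were kept by filterByExpr (16898 IDs, at least 99.95% of the counts of each library), libraries were scaled by TMM, and 1 quasi-likelihood model (glmQLFit, glmQLFTest) was fitted to all 6 libraries with a mean per group, leaving 3 residual degrees of freedom. The 3 groups shared 1 estimate of the spread because 2 libraries per group give little information alone. An ID was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and rose, fell, higher and lower refer to such calls. CPM values are counts relative to the TMM-scaled library size. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. A fold against a group at 0 in both libraries was computed against 3 counts per library and is a lower bound for counting error only. Counts of changes of at least 2-fold use fitted values and were the same with these IDs at their bound; counts of changes of at least 4-fold are given at the bound.

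TMM factors were 0.92 and 0.91 for the control libraries, 1.19 and 1.18 for HCC and 0.92 for both HCC/NAC libraries. Library totals ranged from 33917707 to 37717373 counts. Replicates were compared by their correlation over log2 CPM, by a chi-square test against Poisson sampling over IDs with at least 20 counts in the pair, and by edgeR's biological coefficient of variation within each group. The replicate numbers in the titles are shared by the groups, but nothing in the labels says that a number marks a shared animal, batch or day.

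The method was tested on simulated counts for all 16898 IDs with the real means, library sizes and dispersions and 200 changed IDs per comparison. The changed IDs had a mean CPM of at least 1 and were far fewer than the IDs called in the data. All groups shared 1 dispersion per ID and replicates were independent. Unequal spread between groups, excess zeros and pooled replicates were thus not tested. In HCC against control 84.8% of 4-fold, 71.6% of 2-fold and 35.8% of 1.5-fold changes were recovered, with 7 false calls. In HCC/NAC against control the shares were 89.4%, 53.7% and 28.4% with 7 false calls, and in HCC/NAC against HCC 87.9%, 64.2% and 34.3% with 3 false calls. A missing call for a change under 2-fold is therefore weak evidence of no change. Overlaps between comparisons that share libraries were set beside 20 simulations of unchanged groups and beside the overlap of independent lists. The covariance of HCC minus control and HCC/NAC minus HCC was also computed on log2 CPM with 1 HCC library in each difference. Mixtures of the mean control and HCC profiles were simulated in place of HCC/NAC, 5 times for each share of control tissue.

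Alternatives fixed before the data were examined were RLE and upper-quartile scaling, DESeq2 1.42.0, no low-count filter, a stricter filter (CPM of at least 1 in at least 4 libraries), the replicate number as a block, fits of the 2 groups compared only, a threshold of at least 2-fold, and leaving out each library in turn. Added after the data were seen were a fit to IDs with a mean CPM of at least 10, a fit to counts divided by each library's estimated number of reads per molecule, and limma 3.58.1 (voom) with a weight per library. The number of reads per molecule was estimated from the IDs at 0 in a library among those with 10 to 20 counts in its replicate. Simulated libraries with 1, 5 and 15 reads per molecule gave estimates of 2.15, 5.73 and 13.6. Both libraries of a simulated pair had the same number, so a pair as unequal in low counts as the control pair was not tested.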

Results

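Liver poly(A) RNA was sequenced from male Fischer-344 rats, an inbred laboratory strain, after 16 weeks of treatment. The design text lists 18 rats in 3 groups. Control rats received the oral vehicle alone. The HCC group received diethylnitrosamine (DEN), a DNA-alkylating liver carcinogen, at 50 mg/kg weekly, followed by 2-acetylaminofluorene (2-AAF), an aromatic amine that also acts as a liver carcinogen, at 25 mg/kg. The combination is used to induce hepatocellular carcinoma (HCC) in rats. The HCC/NAC group received the same carcinogens plus N-acetylcysteine (NAC), a cysteine donor for glutathione synthesis, at 300 mg/kg daily. Each group was represented by 2 libraries, made from the pooled RNA of 5 animals per group, so the 6 libraries carried no value for a single animal. The labels call the 2 libraries of a group biological replicates but do not say whether they held different animals, and p-values therefore measured only the spread between these libraries, which may be technical. The count tables identify genes by Ensembl rat gene IDs without symbols, and no ID could be paired with a symbol here. Genes are therefore reported as IDs and as groups defined by their change or abundance. The genes of the KEAP1/NRF2 pathway, the oxidant-response pathway that the series title names, were not analysed here.

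Total counts ranged from 33917707 in HCC replicate 2 to 37717373 in HCC replicate 1, and 16898 gene IDs passed the expression filter. Control livers contained 15646 and 19066 gene IDs with at least 1 count in replicates 1 and 2. In the HCC livers 20317 and 20550 IDs were detected, and in the HCC/NAC livers 17529 and 17684. At 10 or more counts the control replicates differed far less, with 14894 and 14785 IDs. The difference between the control replicates lay at the lowest counts, where control replicate 1 held 336 IDs with 1 to 5 counts and control replicate 2 held 3271. Both HCC/NAC libraries resembled control replicate 1 in this respect, with 632 and 708 such IDs, whereas the HCC libraries held 2847 and 3364. Replicates of a group correlated across gene IDs with r = 0.96 in control, 0.98 in HCC and 0.93 in HCC/NAC livers on the log2 CPM scale. Genes are not independent replicates, and these coefficients describe the libraries only. No replicate pair agreed within Poisson sampling noise, since the chi-square statistic per degree of freedom was 10.2 in control, 5.22 in HCC and 12.2 in HCC/NAC. The spread beyond counting error was wide among weakly expressed IDs: at 1 to 10 CPM the median coefficient of variation was 24.9% in control, 14.5% in HCC and 29.0% in HCC/NAC livers, and over all tested IDs the common coefficient was 26.5%, 8.42% and 35.0%. The replicates lay over 2-fold apart for 17.4%, 6.70% and 17.5% of IDs. For IDs of 100 to 1000 CPM the median coefficient of variation between replicates, beyond counting error, was 5.68% in control, 4.13% in HCC and 6.61% in HCC/NAC livers.

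**Figure D1:**
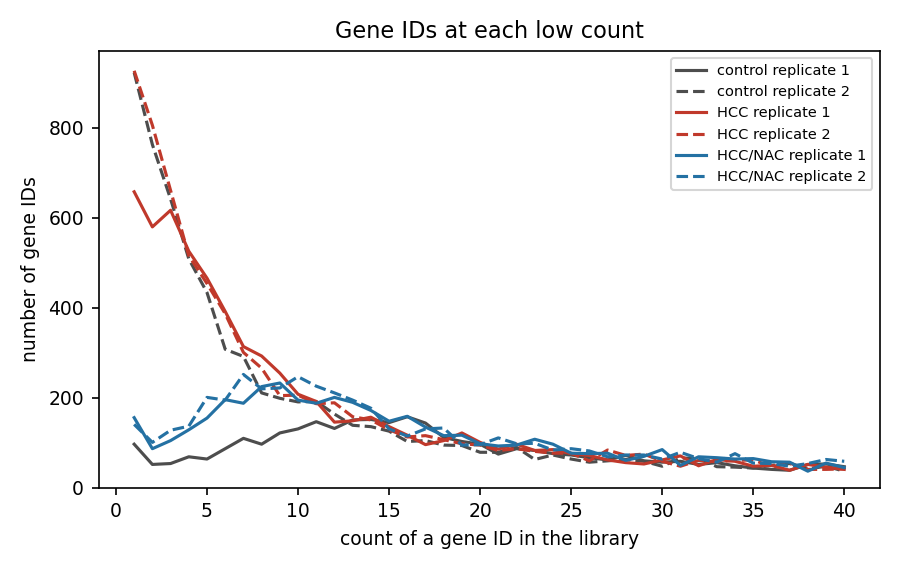
Number of gene IDs (vertical axis) at each count from 1 to 40 (horizontal axis) in the 6 libraries, with colour for the group and line style for the replicate. Control replicate 1 and both HCC/NAC libraries have few IDs at counts of 1 to 5 (336, 632 and 708) beside 2847 to 3364 in the other libraries.

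Control and carcinogen-treated livers separated along the first principal component, which held 56.4% of the variance of log2 CPM. HCC and HCC/NAC livers separated along the second, which held 19.2%. Coefficients between libraries of different groups ranged from 0.88 to 0.90 for control against HCC, from 0.86 to 0.88 for control against HCC/NAC, and from 0.92 to 0.93 for HCC against HCC/NAC. The abundant transcripts also differed. The 10 most abundant gene IDs, ranked by their mean share over all libraries, took 21.4% ± 0.11 (SD, n = 2) of all counts in control, 25.0% ± 0.20 (SD, n = 2) in HCC and 37.6% ± 0.22 (SD, n = 2) in HCC/NAC livers. These were also the 10 most abundant IDs of HCC and of HCC/NAC livers, but not of control livers. The 10 most abundant IDs of control livers, 5 of them shared with that list, took 24.3% ± 0.062 (SD, n = 2) in control, 22.5% ± 0.26 (SD, n = 2) in HCC and 29.4% ± 0.075 (SD, n = 2) in HCC/NAC livers. The share was thus highest in HCC/NAC livers with both rankings, whereas the order of HCC and control turned. The 100 most abundant IDs took 50.3%, 48.1% and 60.7% of counts in control, HCC and HCC/NAC livers. The most abundant ID alone took 4.17% ± 0.077 (SD, n = 2) in control, 7.19% ± 0.10 (SD, n = 2) in HCC and 12.5% ± 0.097 (SD, n = 2) in HCC/NAC livers.

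**Figure D2:**
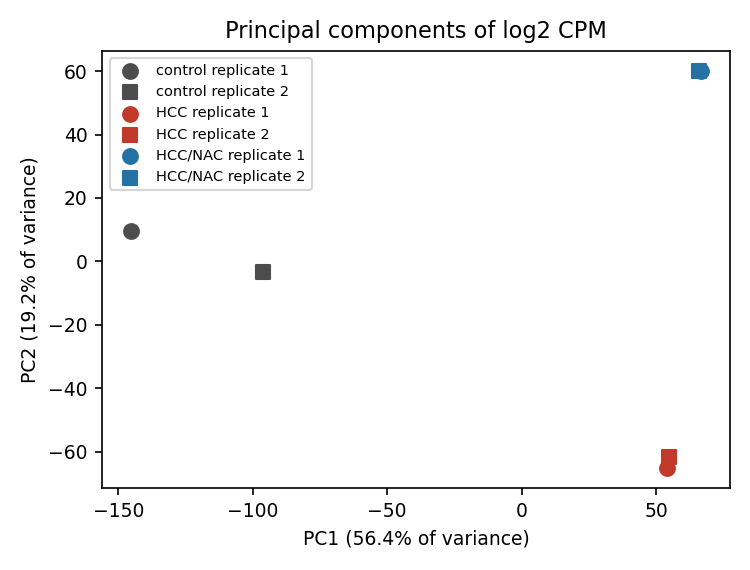
First and second principal components of log2 CPM over 16898 gene IDs, 1 point per library, with colour for the group and marker for the replicate. PC1 (56.4% of the variance) parts control from the carcinogen-treated livers and PC2 (19.2%) parts HCC from HCC/NAC.

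The comparison of HCC with control livers asked how the carcinogen model changed the liver transcriptome. In HCC livers 2876 gene IDs rose and 3007 fell, together 34.8% of those tested. The balance of directions was not stable: rises outnumbered falls in 9 of 17 alternatives, most strongly in number without control replicate 2, with 3357 rises and 2379 falls. The median risen ID was 2.41-fold higher and the median fallen ID 1.71-fold lower, with a median standard error of 0.15 on the log2 scale. Counting IDs absent from a group at their lower bound, 1007 IDs rose and 267 fell by at least 4-fold. Of the IDs with a mean CPM of at least 10, 1522 rose and 2527 fell, whereas below this level 1354 rose and 480 fell. With only the IDs of at least 10 CPM in the fit, an alternative added after the data were seen, 2180 rose and 2205 fell, without the surplus of falls. Control replicate 1 held fewer IDs with 1 to 5 counts (336) than either HCC library (2847 and 3364). Among the 10 most abundant IDs, 6 rose, by 0.54 at most on the log2 scale, and 4 fell, with a lowest log2 fold change of -0.94. Of the 4 falls, 1 had no call in 6 of 16 alternatives: upper-quartile scaling, the stricter filter, a fit of the compared groups only, the fit without control replicate 2, the fit to IDs of at least 10 CPM, and the counts divided by estimated reads per molecule.

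By fitted log2 fold change, the 2 largest rises and the 2 largest falls among IDs of at least 2 CPM on average were between presence and absence. ENSRNOG00000002331 had no count in either control library and reached 96.7 ± 5.7 CPM (SD, n = 2) in HCC livers, at least 1089.5-fold higher than the limit of 3 counts per control library (adjusted p = 9.38e-12, edgeR quasi-likelihood test). ENSRNOG00000010210, also without counts in control, reached 65.6 ± 0.78 CPM (SD, n = 2), at least 739.6-fold higher (adjusted p = 7.81e-11, edgeR). Conversely, ENSRNOG00000081104 fell from 182 ± 3.4 CPM (SD, n = 2) in control, with 6216 and 6118 counts, to 0 counts in both HCC libraries, at least 2578-fold lower (adjusted p = 2.30e-11, edgeR). ENSRNOG00000069670 fell from 58.3 ± 2.8 CPM (SD, n = 2) to 0 counts, at least 825-fold lower (adjusted p = 1.16e-09, edgeR). These folds are lower bounds for counting error only. The estimated reads per molecule, 13.9 and 7.30 in the control and 4.93 and 4.45 in the HCC libraries, exceed the limit of 3 counts, so the folds may be lower. The genomic positions and annotations of these IDs were not analysed here. In all, 41 IDs had no count in either control library and 100 or more in both HCC libraries, and 5 IDs showed the reverse. All 5 of the latter were also at 0 in both HCC/NAC libraries.

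These calls came from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05, fitted to all 6 libraries. The deposited file names carry 1 prefix for both control libraries and another for all 4 carcinogen-treated libraries. If this prefix marks a batch, the batch and the carcinogen treatment cannot be told apart.

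The comparison of HCC/NAC with control livers measured how far livers remained from control when NAC was given with the carcinogens. In HCC/NAC livers 3599 IDs rose and 4208 fell against control, 46.2% of those tested. Rises outnumbered falls in 8 of 17 alternatives, among them upper-quartile scaling with 4291 rises and 3536 falls and the fit without control replicate 2 with 4019 and 3438. The median risen ID was 2.40-fold higher and the median fallen ID 1.92-fold lower. With absent IDs at their lower bound, 1093 IDs rose and 511 fell by at least 4-fold. Among the 10 most abundant IDs, 8 rose and 2 fell. ENSRNOG00000002331 and ENSRNOG00000010210 were at least 1023-fold and 330.6-fold higher than in control (adjusted p = 1.20e-11 and 3.42e-10, edgeR), and ENSRNOG00000081104 and ENSRNOG00000069670 were again at 0 counts in both libraries. More IDs were called than in HCC against control, except in 3 of 17 alternatives. These were the compared groups only, counts divided by estimated reads per molecule, and voom with a weight per library.

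Most IDs changed in HCC livers were changed in the same direction in HCC/NAC livers. Of the 2876 that rose in HCC, 2112 also rose in HCC/NAC against control, 106 fell there and the others had no call. Of the 3007 that fell in HCC, 2365 also fell in HCC/NAC and 93 rose. Independent lists of these sizes would share 612.5 risen and 748.8 fallen IDs. Both comparisons used the same 2 control libraries, and 20 simulations of unchanged groups against shared controls gave no shared call; they made at most 4 calls in a comparison, so this count says nothing about the overlap of lists with real changes. Across IDs the log2 fold changes correlated with r = 0.80, beside a mean of 0.51 in the simulations. Their covariance was 3.11, beside a simulated mean of 0.33. With 2 control libraries the controls could not be split into parts of 2, and part of the overlap beyond that of independent lists may come from the shared controls. If the file name prefix marks a batch, it could also shift HCC and HCC/NAC alike against control and add to this overlap.

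**Figure D3:**
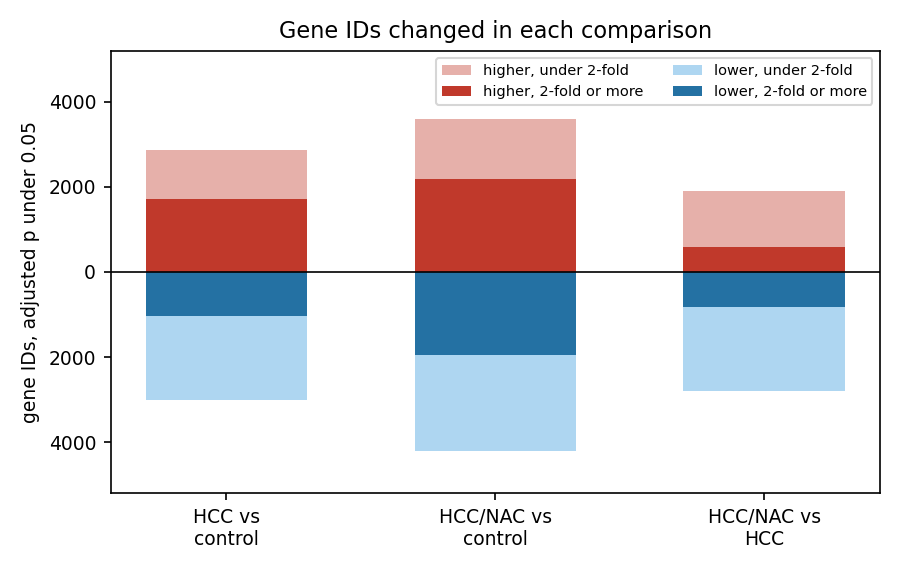
Number of gene IDs with adjusted p under 0.05 (edgeR) in the 3 comparisons, with higher IDs above the zero line and lower IDs below it; dark parts are changes of at least 2-fold. In this fit HCC/NAC against control has the most calls (3599 higher, 4208 lower), as in 14 of 17 alternatives. HCC against control is ahead in the other 3. These are the fit of the compared groups only (6729 against 6618 calls) and counts divided by reads per molecule (6716 against 6685). The last is voom with a weight per library (7080 against 7009). They estimate spread per comparison, rescale counts per library, or weight each library. HCC/NAC against HCC has the fewest calls (1899 higher, 2787 lower), as in 16 of 17.

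The direct comparison of HCC/NAC with HCC livers measured the effect of NAC in carcinogen-treated animals. With NAC, 1899 IDs were higher and 2787 lower, 27.7% of those tested. The groups also differed in their low counts: of IDs with 20 to 50 counts in the replicate partner, 13.4% and 10.9% were at 0 in the HCC/NAC libraries and 0.11% and 0.46% in the HCC libraries. The median ID was 1.67-fold higher among the risen and 1.66-fold lower among the fallen, and 592 and 830 IDs changed at least 2-fold. Of the 10 most abundant IDs, 9 rose with NAC, by 0.43 to 1.47 on the log2 scale, and 1 fell by 0.60. These 9 rises and 1 fall had the same calls under each scaling tried. What these IDs encode was not analysed here, and whether the 9 rises are separate responses or 1 shared shift was not tested. Of the 2 IDs most raised by the model, ENSRNOG00000010210 fell with NAC from 65.6 ± 0.78 to 29.3 ± 2.6 CPM (SD, n = 2 each), a log2 fold change of -1.16 ± 0.12 (SE; adjusted p = 2.86e-05, edgeR). ENSRNOG00000002331 stayed at 90.8 ± 2.9 CPM (SD, n = 2), with a log2 fold change of -0.09 ± 0.09 (SE; adjusted p = 0.504, edgeR). Only 3 IDs had 100 or more counts in both HCC libraries and 0 in both HCC/NAC libraries, and none showed the reverse (0 IDs).

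The surplus of lower over higher IDs in this comparison was found in 16 of 17 alternatives, but not when the fit was restricted to IDs of a mean CPM of at least 10, where 2067 were higher and 1995 lower. In the fit to all tested IDs, 1479 of the IDs at this level were higher and 2172 lower. The surplus was smaller under other scalings, with 2173 higher and 2459 lower under RLE and 2194 and 2406 under upper-quartile scaling. Without HCC replicate 1 the number of calls dropped from 4686 to 3093.

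Whether NAC moved the model's changes back toward control was examined among the IDs called in HCC against control. Of the 2876 IDs that rose in HCC livers, 788 were lower with NAC, 301 were higher still and 1787 had no call between HCC/NAC and HCC. Of the 3007 that fell, 779 were higher with NAC, 768 were lower still and 1460 had no call. Changes opposite to the model's thus numbered 1567 IDs, and changes further in the model's direction 1069. Among the risen IDs the opposite changes outnumbered the others in all 17 alternatives. Among the fallen IDs they did so in 12, such as 852 against 655 with RLE scaling and 791 against 559 with IDs of at least 10 CPM, and the reverse held in 5, such as 759 against 923 without HCC/NAC replicate 1. Independent lists of the same sizes would give 812.3 opposite and 819.2 same-direction IDs. Among the 788 risen IDs that were lower with NAC, 361 remained above control, 321 had no call against control and 106 lay below it. Among the 779 fallen IDs that were higher with NAC, 374 remained below control, 312 had no call against control and 93 lay above it. Over all 3007 fallen IDs, with or without a second call, 48.5% lay closer to control in HCC/NAC than in HCC. Their median log2 fold change against control was -0.78 in HCC and -0.87 in HCC/NAC. Over all 2876 risen IDs 62.9% lay closer, with medians of 1.27 and 1.18.

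The HCC libraries entered both comparisons with opposite sign, which makes their fold changes covary negatively without any effect. The observed correlation across IDs was -0.21, weaker than the simulated mean of -0.48 (range -0.51 to -0.46). The observed covariance was -0.51, beside a mean of -0.31 and a lowest value of -0.34 in 20 simulations without effects. For IDs with a mean CPM of at least 10 the covariance was -0.16, beside a simulated mean of -0.01. With 1 HCC library in each comparison, so that none was shared, the covariance of log2 CPM differences was -0.27 and -0.26 under the 2 assignments, beside -0.01 to 0.01 in the simulations. The simulated libraries were independent, so error common to both HCC libraries, as from 1 pool of animals, was not tested. The HCC libraries could not be split into parts of 2 for a test, and part of the excess of calls over independent lists may come from their shared error. Leaving out HCC replicate 1 or HCC replicate 2 reduced the opposite IDs to 957 and 1003, and the same-direction IDs to 631 and 670. Control replicate 1 and both HCC/NAC libraries lacked low-count IDs beside the HCC libraries; with counts divided by the estimated reads per molecule 1959 IDs were opposite and 1283 in the same direction.

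**Figure D4:**
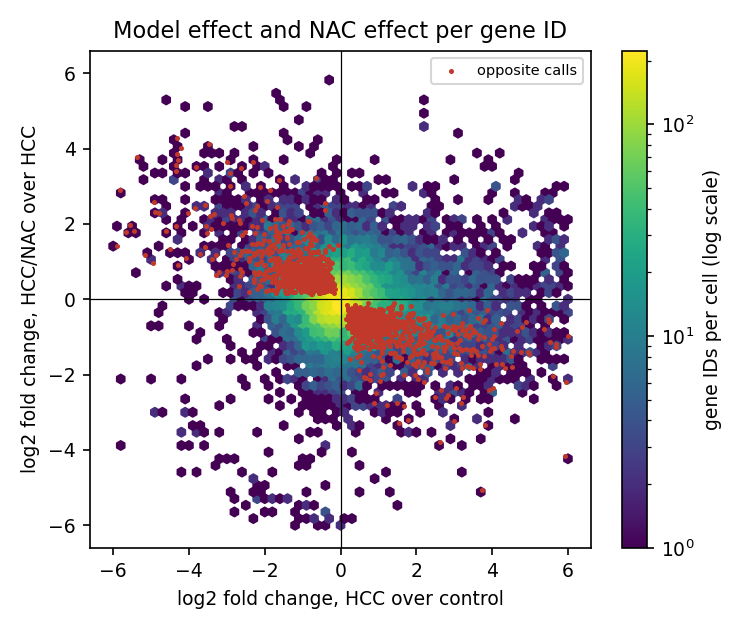
Log2 fold change of HCC over control (horizontal axis) against that of HCC/NAC over HCC (vertical axis) for 16205 gene IDs within 6 log2 units on both axes, with 693 outside; colour gives the number of IDs per cell on a log scale. Red points mark IDs with calls in opposite directions (1567 in all, including those outside the axes).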

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

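The last 3 alternatives named in the processing account were chosen after the data were seen; the others were set before. Apart from the 2-fold threshold, calls ranged over 16 alternatives from 4254 to 7080 for HCC against control, from 5247 to 8061 for HCC/NAC against control and from 3093 to 5452 for HCC/NAC against HCC. Of all alternatives to the 6 counts, 91 of 102 lay within 1.5 times of the reported count. No ID called as reported was called in the opposite direction, except 4 IDs of HCC/NAC against control when only IDs with a mean CPM of at least 10 were fitted. All 156 alternative values of the 4 named IDs kept their side of the threshold, and all called values their direction. The uncalled log2 fold change of ENSRNOG00000002331 between HCC/NAC and HCC changed from -0.09 to 0.0018 with IDs of a mean CPM of at least 10. The stricter filter left ENSRNOG00000081104 and ENSRNOG00000069670 untested. The 4 IDs were picked for their large changes in these data, so their kept calls say little about robustness. Requiring at least a 2-fold change reduced the calls, by construction, to 2738, 4147 and 1422 in the 3 comparisons, the opposite calls to 390, the same-direction calls between HCC and the NAC effect to 77, and the calls shared by HCC and HCC/NAC against control to 1933. Leaving out 1 library gave 3093 to 5075 calls for HCC/NAC against HCC, 957 to 1676 opposite and 631 to 1219 same-direction calls. The lowest values came without HCC replicate 1, where 1 HCC library was left and assumed to vary like the other groups. Leaving out 1 HCC/NAC library lowered the HCC/NAC against HCC calls far less or not at all. That fit also took the HCC/NAC pair, which had the widest spread, out of the shared estimate. It therefore cannot tell the loss of samples from the change in spread. The HCC pair had the narrowest spread, with a common coefficient of variation of 8.42% beside 26.5% in control and 35.0% in HCC/NAC livers. Leaving out an HCC library also lowered the calls of HCC/NAC against control, which lost no compared library. Leaving out an HCC/NAC library raised those of HCC against control. The shared fit thus moved the counts, though the parts of spread, filter and scaling were not separated. Upper-quartile scaling moved the median log2 fold change of HCC/NAC against control by 0.14. Of the HCC/NAC against HCC calls, 40.5% were higher as reported and 50.9% with IDs of a mean CPM of at least 10. Lower IDs outnumbered higher ones in the other 16 of 17 alternatives. Among IDs of that level 1479 were higher and 2172 lower in the fit to all IDs, so the choice of IDs counted is not what moved the balance. Scaling had a part: in the fit to IDs of that level the log2 fold change of ENSRNOG00000010210 also moved upward, from -1.16 to -1.07. The surplus of lower IDs was smaller with RLE (2173 higher, 2459 lower), upper-quartile scaling (2194 and 2406) and DESeq2 (2058 and 2399). The part of the estimated spread was not separated. Same-numbered replicates did not deviate together (r from -0.01 to 0.01 across IDs). With the replicate number as a block the calls numbered 5982, 7650 and 4861. Planned tests of gene lists, the NRF2 targets among them, were not run because the IDs had no symbols. Totals of 33917707 to 37717373 counts leave little difference in depth between libraries.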

Other observations

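Of the tests in this part, the share of zeros among IDs with 20 to 50 counts and the covariance with no shared library were set out before their values were seen. The count of opposite calls, the stricter filter and leaving out each library were planned before the data were examined. The others were chosen afterwards. Some gene IDs stood apart in HCC/NAC livers from both other groups. Without a call between HCC and control, 660 IDs were higher in HCC/NAC than in both control and HCC livers, and 1044 were lower than in both (edgeR quasi-likelihood test, adjusted p under 0.05 in both comparisons). These 2 counts were not recomputed under the alternatives, and the surplus of lower over higher IDs against HCC varied with scaling and the IDs fitted. A missing call between HCC and control is weak evidence of no change under 2-fold. Of the 41 IDs absent from both control libraries with 100 or more counts in both HCC libraries, 13 also reached 100 counts in both HCC/NAC libraries, and 2 were at 0 in both.

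Control replicate 1 and both HCC/NAC libraries held few IDs with 1 to 5 counts at a depth like that of the others. Lower depth is argued against by the total of control replicate 1, 1.04 times that of control replicate 2, and a minimum count set before deposit by the 336 or more IDs with 1 to 5 counts that each of the 3 libraries kept. Low library complexity, few molecules amplified into many reads, is consistent with the zeros: of IDs with 20 to 50 counts in the replicate partner, 11.5%, 13.4% and 10.9% were at 0 in control replicate 1 and HCC/NAC replicates 1 and 2, against 2.95% in control replicate 2 and 0.11% and 0.46% in the HCC libraries. Control replicate 1 received no NAC by design; for the HCC/NAC libraries NAC stays open, since the share at 0 in control replicate 1 minus the higher of theirs was -1.97 percentage points, with overlapping exact binomial 95% intervals. Dividing counts by the estimated reads per molecule left 12066 IDs past the filter in place of 16898 and gave 6716, 6685 and 5044 calls in the 3 comparisons, with 2475 IDs higher and 2569 lower in HCC/NAC against HCC, beside 1899 and 2787 from the counts as deposited.

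Changes with NAC opposite to those of the model outnumbered changes in the same direction, 1567 to 1069 (788 against 301 among the risen IDs and 779 against 768 among the fallen, where the balance varied, with 909 against 676 under the stricter filter and 759 against 923 without HCC/NAC replicate 1). Error that is independent between the 2 HCC libraries does not account for all of the opposite changes. With 1 HCC library in each comparison the covariance was -0.27 and -0.26 (-0.17 and -0.15 for IDs of at least 10 CPM), where 20 simulations without effects gave -0.01 at the lowest. Error common to both HCC libraries, as from 1 pool of animals, stays open. It would remain after the split, and the simulated libraries were independent. With shared libraries the correlation of -0.21 was weaker than the simulated -0.48, while the covariance of -0.51 was below the simulated -0.31; shared error adds a fixed covariance, and real changes add variance that lowers a correlation. A dilution of HCC tissue by control-like tissue in the NAC-treated livers would move IDs only toward control: simulated mixtures with 0.1 to 0.75 of control tissue gave at most 2 IDs farther from control, and the 1069 observed argue against it as the whole cause. The simulated mixtures held no difference in complexity between libraries. The fit to IDs of at least 10 CPM, where low counts matter less, still gave 1070 same-direction IDs. A partial attenuation of the model's response by NAC together with changes of its own remains an untested hypothesis. Over all IDs that fell in HCC, with or without a second call, 48.5% lay closer to control with NAC, and of those that rose 62.9%. The median fallen ID lay farther from control with NAC, at a log2 fold change of -0.87 beside -0.78 in HCC. Differences in the number or size of lesions in the sampled tissue stay open and untested. So does a part of library complexity, in which the HCC libraries stand apart from control replicate 1 and HCC/NAC (1959 opposite and 1283 same-direction IDs with divided counts).

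A set of 5 IDs with 100 or more counts in both control libraries had 0 counts in all 4 carcinogen-treated libraries, the highest with 6216 and 6118 control counts. Repression by the carcinogen treatment may explain this, and 2 other IDs of 1000 or more control counts ended at 1 to 10 counts in the treated libraries. A batch or genotype difference between control and treated animals would give the same picture. The 2 explanations cannot be told apart for these 5 IDs, because the prefix of the file names splits the libraries exactly as the treatment does.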
